A study of Mus musculus with 3186 samples.

How the data were processed

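The sources were the sample and series labels with the submitters' processing notes and the deposited files. Per the labels, single cells from adult mouse brain were sorted by reporter fluorescence into 384-well plates and full-length complementary DNA was made and sequenced by the Smart-seq2 method. The notes name STAR 2.4.2a as the aligner and mm10 as the genome; the gene counter, the gene annotation and the filters for genes and cells are not given in the sources used here. The deposited count tables hold reads per gene and cell, whole numbers without molecular tags, for 3186 cells and 19937 genes. Every column was matched to 1 sample, no pair of cells had identical counts, and there were no mitochondrial symbols and no ERCC spike-in symbols. The authors' scaled tables sum to between 499421 and 501418 per cell, and 99.6% of their non-zero values lie within 0.75 of a constant multiple of the count (largest distance 78.0). Gene positions were taken from the GENCODE M21 annotation of mm10, in which 18871 symbols were found.

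Counts were used as deposited. A minimum of 500 genes per cell removed 0 cells. All cells were clustered on a seeded random set of 50% of the genes that left out every member of the gene lists and the reporter genes, so that a list was never tested on cells grouped by it. For each clustering the 2000 most variable genes read in at least 1% of cells were reduced to 30 principal components, joined to 15 nearest neighbours and grouped by the Leiden method at resolution 1 with seed 1. Endothelial-like and mural-like cells were clustered again within their class. Each cluster received a naming score, computed here per the labels of 18 fixed marker sets: the share of a set's markers that reached 50% of the highest cluster's level. The set with the highest score gave the name if over 50% of its markers were high and at least 3 had 20 CPM. A cluster stayed unnamed if 2 or more markers of another class, and more than its own, were among its 10 leading genes, with markers matched by exact symbol. This last part of the rule was set after the data were seen. The whole rule left 13.0% of the Cldn5-eGFP cells, 5.19% of the Pdgfrb-eGFP/NG2-dsRed cells and 3.89% of the Pdgfra-H2BGFP cells in unnamed sub-clusters. Composition used the broad classes, and the comparisons used named sub-clusters alone. Wells whose summed markers of another class reached 10% of that class's median were called mixed as possible doublets (476 of 3186 cells, 14.9%, with 29.0% of pericyte-like, 22.7% of smooth muscle-like, 44.9% of fibroblast-like, 42.9% of microglia-like, 0.645% of oligodendrocyte-like and 2.35% of endothelial-like cells) and kept, with an alternative that left them out. Some markers were read widely in other classes, such as the endothelial marker Emcn at 488 CPM in pericyte-like and 1021 CPM in fibroblast-like cells. These shares are therefore not rates of doublets.

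Each line or class was summed to 1 pool and given as CPM (counts scaled by total reads) with exact Poisson intervals, and shares of cells with exact binomial intervals, all at 95%. The labels name no animals, so no test, standard error or count of changed genes was computed. Plates, which lie within lines, gave a range where they held at least 10 cells. The labels do not tie plates to animals, so this range may hold differences between animals beside technical ones. Log2 ratios used a pseudocount of 1 CPM. A fold over a group with no read was bounded with 3 counts. The 17 gene lists were fixed before the data were examined: blood-brain barrier transporters, junction genes, Wnt and beta-catenin pathway, caveolae and transcytosis, leukocyte adhesion and inflammation, Notch pathway, contractile apparatus, basement membrane, interstitial matrix, vascular growth factors and receptors, mural signalling and channels, oxidative phosphorylation, glycolysis, lipid and retinoid handling, immediate early and stress, cell cycle, and a sex-linked check. List members counted with at least 5 CPM on either side, and a list's median was ranked among 10000 random lists drawn from the same 20 bins of mean expression. In the files 2 of the 35 growth factor and receptor genes (Gucy1a1 and Gucy1b1, there under the symbols Gucy1a3 and Gucy1b3) and 1 of the 13 cell cycle genes (Ccnb1) were missing. Genes were named by rule: the 10 largest log2 ratios in each direction with at least 50 CPM and reads in 25% of cells, and up to 3 members at each end of a list with at least 20 CPM. The first group left out clustering features, markers and reporter genes. Classes that shared at least 2 plates had to differ at least 2-fold in the same direction on each. Between lines, the lowest plate of the higher line had to lie above the highest plate of the lower. Agreement between plates in these genes thus follows from the choice. For 2 list members the values of the single gene are not reported here, while the lists were used whole. All steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.

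The steps were tried on simulated plate sums with the sizes of the arterial-like over capillary-like comparison and the levels of capillary-like cells, in which 50 of 9719 genes had each of 4 known changes. Genes raised 4-fold had a median log2 ratio of 1.95 and genes lowered 4-fold of -1.89, and 100% of both passed 2-fold. Genes raised 2-fold had a median of 0.91 and genes lowered 2-fold of -0.97, of which 22% and 38% passed, so the count of list members at 2-fold misses changes of that size. Of the 9519 unchanged genes 0 passed. A list of 20 raised genes ranked at percentile 100, and 5 of 100 unchanged lists fell in the outer 5%. The spread between simulated plates was a setting not estimated from these data, genes varied independently, and cells were neither drawn nor clustered. These rates therefore hold for that setting alone. In the data leaving out a plate moved some genes further: without EC5 the arterial-like over capillary-like log2 ratio of Bgn went from 2.03 to -0.59. Results were recomputed under 57 other settings fixed in advance, and 8 more were added after the data were seen. The 57 covered the clustering, the cells kept, the scaling, the pseudocount, the list minimum, the within-plate mean and leaving out each plate. Not every result was recomputed under each setting. Clustering at resolutions 0.5 and 2 and on the authors' values was applied to class shares alone, so lists and genes have no values there.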

Results

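RNA was sequenced from 3186 single cells sorted from the brains of adult C57BL/6 mice aged 12 to 15 weeks, with 1 library per cell. The cells came from 3 reporter lines in which a fluorescent protein marks a cell population: 1445 cells from Cldn5-eGFP mice, where the promoter of a tight junction gene marks endothelium, 1484 cells from Pdgfrb-eGFP/NG2-dsRed mice, where both reporters mark mural cells, and 257 cells from Pdgfra-H2BGFP mice, where a perivascular population and the oligodendrocyte lineage are labelled. They lay on 10 plates of 384 wells, 4 plates for Cldn5-eGFP, 4 for Pdgfrb-eGFP/NG2-dsRed and 2 for Pdgfra-H2BGFP. Each cell had between 99905 and 1606954 reads in genes (median 350339) and between 839 and 7462 genes with a read (median 2488). The median number of reads per cell was 345991 in the Cldn5-eGFP line, 340344 in the Pdgfrb-eGFP/NG2-dsRed line and 533187 in the Pdgfra-H2BGFP line. The labels name no animal, so each line counted as 1 sample: there are no replicates, no difference has a test, and intervals and floors cover only the counting error of reads without molecular tags.

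Endothelial-like cells made up nearly the whole Cldn5-eGFP line (1442 of 1445 cells, 99.8%, exact 95% interval 99.4 to 99.957). The Pdgfrb-eGFP/NG2-dsRed line held mainly pericyte-like cells, the mural cells of capillaries (1216 of 1484, 81.9%, 79.9 to 83.9), with smooth muscle-like cells, the contractile mural cells of larger vessels (176 cells, 11.9%, 10.3 to 13.6), and endothelial-like cells (85 cells, 5.73%, 4.60 to 7.03), of which 33 lay in an unnamed sub-cluster led by mural genes such as Vtn, Atp13a5 and Pdgfrb. The broad pericyte-like class included 13 cells of an unnamed sub-cluster led by endothelial genes such as Cldn5 and Slco1a4, and the named pericyte-like sub-clusters held 1181 cells (79.6%). Across the 4 plates the broad pericyte-like share lay between 79.9% and 84.9% and the smooth muscle-like share between 11.7% and 12.2%. The Pdgfra-H2BGFP line held oligodendrocyte-like cells, which make myelin (155 of 257, 60.3%, 54.04 to 66.3), fibroblast-like cells (78 cells, 30.4%, 24.8 to 36.4), microglia-like cells (11 cells, 4.28%) and 10 cells (3.89%) of the broad pericyte-like class. These 10 all fell in an unnamed mural sub-cluster led by Moxd1 and Coch, which also lead a fibroblast-like cluster, and no named pericyte-like sub-cluster held a cell of this line (0 of 257). Its plates differed: fibroblast-like cells were 48.6% of plate Pdgfra1 and 17.3% of plate Pdgfra2, and oligodendrocyte-like cells were 35.5% and 78.0%. No fibroblast-like cell was found among the Pdgfrb-eGFP/NG2-dsRed cells (0 of 1484, exact upper limit 0.248%) or the Cldn5-eGFP cells (0 of 1445, 0.255%). These limits hold for the named class alone: 25 cells of the Pdgfrb-eGFP/NG2-dsRed line (1.69%) lay in the mural sub-cluster led by Moxd1 and Coch, where fibroblast markers summed to 3199.7 CPM against 838 in pericyte-like cells and pericyte markers to 23189 CPM. The fluorescence sort sets these shares. Of the 18 marker sets, the 8 for oligodendrocyte progenitors, perivascular macrophages, astrocytes, neurons, ependyma, choroid plexus epithelium, T or NK cells and neutrophils named no cluster. The erythroid set, of which 2 of 5 markers were matched, could not name 1, and the neutrophil set rested on 3 of 5. The erythroid marker Hbb-bt was in the files under the joint entry Hbb-b2+Hbb-bt, which was not matched. A set that named no cluster does not show that its cells were absent. Perivascular macrophage markers summed to 2355 CPM in microglia-like cells, and oligodendrocyte progenitor markers to 2760 CPM in oligodendrocyte-like cells.

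**Figure D1:**
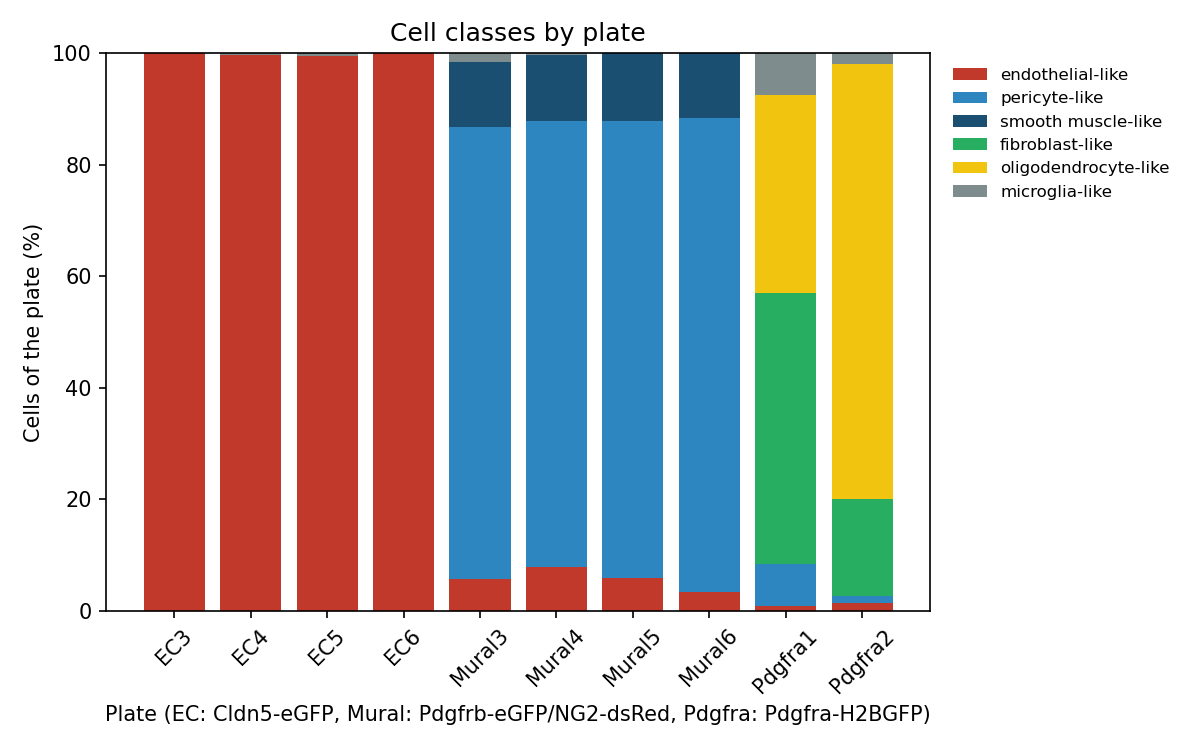
Share of each cell class (y axis, percent of the plate's cells) on each of the 10 plates (x axis), as stacked bars coloured by class. The 4 plates of the Cldn5-eGFP line are nearly all endothelial-like, the 4 plates of the Pdgfrb-eGFP/NG2-dsRed line hold 79.9% to 84.9% pericyte-like cells, and the 2 plates of the Pdgfra-H2BGFP line hold 48.6% and 17.3% fibroblast-like cells.

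Within the 1530 endothelial-like cells of all lines, 788 were capillary-like (51.5%, 48.97 to 54.04), 263 arterial-like (17.2%, 15.3 to 19.2) and 252 venous-like (16.5%, 14.6 to 18.4). On the 4 Cldn5-eGFP plates the arterial-like share ranged from 14.7% to 20.6%, the capillary-like share from 48.9% to 55.4% and the venous-like share from 13.2% to 19.8%. A sub-cluster of 192 cells and the mural-led sub-cluster, of 35 cells, took no name. The largest capillary-like sub-cluster (360 cells) was led by Apln and Angpt2. Its 10 leading genes held the erythroid marker Alas2, the joint entry Hbb-b2+Hbb-bt and no capillary marker. The fixed erythroid marker Hbb-bt was not matched to this joint entry. With that entry counted, the naming rule would leave this sub-cluster unnamed. A stricter rule, added after the data were seen, did so, and the capillary-like share was then 27.97%. Other clustering settings moved these shares by over 1.5 times: at a clustering resolution of 0.5 no sub-cluster was venous-like, and at a resolution of 2 the arterial-like share was 4.33%. Comparisons of the endothelial classes were not recomputed at these resolutions.

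The reporter genes checked the labels. Cldn5, the tight junction claudin of brain endothelium, had 27893 CPM (pooled counts scaled by total reads) in the Cldn5-eGFP line, 248 in the Pdgfrb-eGFP/NG2-dsRed line and 37.4 in the Pdgfra-H2BGFP line. Pdgfrb, the receptor that recruits mural cells, had 0.153, 4287 and 339.95 CPM in the same order, and Cspg4, which encodes the NG2 proteoglycan, 22.1, 1909 and 85.9 CPM. Pdgfra, the receptor for platelet-derived growth factor A, had 0.512, 0.188 and 130.6 CPM. The transcript of eGFP itself had 28173 CPM in the Cldn5-eGFP line, 2085 in the Pdgfrb-eGFP/NG2-dsRed line and 36.6 in the Pdgfra-H2BGFP line. Within that line plate Pdgfra1 had the higher levels of most of these: Pdgfra had 197 CPM on it and 25.7 on Pdgfra2, eGFP 53.0 and 10.7, Pdgfrb 515 and 64.9, and Cspg4 104.0 and 57.4. Cldn5 went the other way, with 31.3 and 47.1 CPM.

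The first comparison set the lines that mark endothelium and mural cells side by side, with ratios given as Cldn5-eGFP over Pdgfrb-eGFP/NG2-dsRed. The Cldn5-eGFP line had more RNA of blood-brain barrier transporters: 20 of 23 were at least 2-fold higher than in the Pdgfrb-eGFP/NG2-dsRed line and 1 lower, with a median log2 ratio of 3.65. Among them were Slc38a3, a glutamine transporter (1195 against 60.9 CPM), and Slc6a6, the taurine transporter (3673 against 195 CPM), while the nucleoside transporter Slc29a1 was lower (36.9 against 186 CPM). Of 12 junction genes, 8 were higher, Lsr of tricellular junctions most (log2 ratio 4.43). The mural line had all 20 genes for mural signalling and channels at least 2-fold higher (median log2 ratio -5.12) and 22 of 25 contractile genes (median -3.58). Its most shifted genes among those that passed the naming rule included Atp13a5, a cation-transporting ATPase (1.58 against 7962 CPM, 7194 to 8725 over the mural plates, log2 ratio -11.59), Gucy1b3, a subunit of the nitric oxide receptor guanylate cyclase (0.143 against 1139.7 CPM), Enpep, the aminopeptidase that cleaves angiotensin II (log2 ratio -9.78), and the myosin light chain Myl9 (log2 ratio -9.40). Medians of the transporter and junction lists lay at percentiles 100 and 99.99 among 10000 random lists matched on mean expression, and those of the contractile and mural lists at 0. The mural signalling list includes Cspg4, the gene of the NG2 reporter in the mural line, so that member is no finding. The mural line included the 85 endothelial-like cells, line and plate changed together, and the median over all 11112 genes was -0.12.

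The Pdgfra-H2BGFP line differed from both vascular lines in matrix and lipid genes. Of 25 interstitial matrix genes, 24 were at least 2-fold higher than in the Cldn5-eGFP line (median log2 ratio 5.45) and 20 higher than in the Pdgfrb-eGFP/NG2-dsRed line (median 2.52); both medians lay at percentile 100. Mfap4, a microfibril-associated glycoprotein, had 342 CPM (339 to 345) and no read in the other 2 lines, which makes it at least 55903-fold and 56934-fold higher by the count of 3 that a 0 allows over the group. Ptgds, which makes prostaglandin D2, had 9520.1 CPM (6775 and 13841 on the 2 plates) against 4.47 and 3.00, and Apod, a lipid-binding apolipoprotein, 7409 against 163 CPM in the mural line. Oligodendrocyte transcripts were also high, such as Opalin, a myelin membrane protein (831 CPM against 0.006 in the Cldn5-eGFP line and 0.226 in the Pdgfrb-eGFP/NG2-dsRed line), and Fa2h, which hydroxylates myelin lipids (721 against 0.014 and 0.120 CPM). Genes for lipid and retinoid handling were higher in 18 of 20 cases against endothelium and 16 of 20 against the mural line.

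Lower in the Pdgfra-H2BGFP line than in the Cldn5-eGFP line were 21 of 23 blood-brain barrier transporters (median log2 ratio -4.61), led by the thyroid hormone transporter Slco1c1 (5.04 against 2584 CPM), with Robo4, a guidance receptor of endothelium (2.77 against 663 CPM). Against the mural line, 22 of 25 contractile genes were lower (median -2.40), such as Kcnmb1, a subunit of the large-conductance potassium channel (2.24 against 291 CPM). The plates of this line differed in cell classes and in many of these levels: without plate Pdgfra1 the log2 ratio of Mfap4 was 5.83 against each line, that of Slco1c1 -7.74, and the count of matrix genes higher than in the mural line 12; without Pdgfra2 these were 9.04, -10.20 and 21. The log2 ratio against the Cldn5-eGFP line of Fa2h, 9.47, was 10.23 without Pdgfra1 and 8.65 without Pdgfra2, against the mural line 9.33, 10.09 and 8.51, that of Robo4, -7.46, was -6.81 and -8.10, and Kcnmb1 went from -6.49 to -7.39 without Pdgfra1. Without EC6 the log2 ratio of Ptgds against the Cldn5-eGFP line was 11.89 in place of 10.77.

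The central comparison asked how the vessel wall's inner and outer cells differ, with 1303 endothelial-like against 1181 pericyte-like cells, those of the named sub-clusters. Nearly all the endothelial-like cells came from the Cldn5-eGFP line and all the pericyte-like cells from the Pdgfrb-eGFP/NG2-dsRed line. Class, line and plate therefore changed together for most cells. The 3 plates with both classes held 8, 12 and 13 capillary-like cells and at most 2 of each other named endothelial class. Values within plates thus rest on few endothelial-like cells. A pericyte-like sub-cluster of 269 cells, with all 8 pericyte markers high, had the choroid plexus marker Ttr and no pericyte marker among its 10 leading genes. Endothelial-like cells had Clec14a, an endothelial surface lectin, at 417 CPM (95% interval 415 to 419) against 0.383 (0.324 to 0.450), a log2 ratio of 8.24 and of 7.85 to 8.63 within the 3 plates that held both classes. Pericyte-like cells had Atp13a5 at 9959.7 CPM against 8.35 (log2 ratio -10.06, within plates -6.62 to -5.37), the imino acid transporter Slc6a20a at 1691 against 0.882, and P2ry14, a receptor for UDP-sugars, at 2598 against 3.39. In the mm10 annotation Clec14a lies on chromosome 12 from 58264720 to 58269290 and Atp13a5 on chromosome 16 from 29231851 to 29378732.

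Of 23 blood-brain barrier transporters, 20 were at least 2-fold higher in endothelial-like cells and 1 lower (median log2 ratio 5.55, percentile 100). The largest ratios were those of the organic anion transporters Slco2b1 (716 against 1.78 CPM) and Slco1a4 (4594 against 21.7) and of the drug efflux pump Abcb1a (1090.2 against 4.61). Another organic anion transporter, Slc22a8, had 1350.5 CPM in endothelial-like and 1396 CPM in pericyte-like cells, and Slc29a1 was lower in endothelial-like cells (log2 ratio -2.29). Of 12 junction genes 8 were higher (median 2.86, percentile 99.99), among them Lsr and occludin (Ocln, 652 against 10.7 CPM), and of 18 genes of the Wnt and beta-catenin pathway, which maintains the barrier, 11 were higher (median 1.34, percentile 99.98). These included the transcription factor Sox17 (299 against 1.23 CPM) and the Wnt receptor Fzd4 (74.0 against 1.32), while the co-receptors Lrp5 and Lrp6 both had a log2 ratio of -0.41. Reads of near-identical copies, such as Abcb1a and Abcb1b, Hspa1a and Hspa1b, or Ddx3y and Eif2s3y with their X-linked relatives, are uncertain in their assignment.

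Contractile genes were lower in endothelial-like cells for 14 of 22 members and higher for 2 (median log2 ratio -2.46, percentile 0): Myl9 had 24.3 against 3998 CPM, and the exceptions were Synpo2 and Csrp1, which bind actin structures (log2 ratios 5.11 and 2.68). The pericyte-like class includes a sub-cluster of 135 cells with more Acta2 RNA than the other pericyte-like sub-clusters, described at the end. This comparison was not recomputed without it. All 19 counted genes of mural signalling and channels were lower in endothelial-like cells (median -4.74, percentile 0). Pericyte-like cells were named by markers that include channel genes outside this list, such as Kcnj8 and Abcc9, so its rank against endothelial-like or fibroblast-like cells is no independent result. The list also includes the reporter gene Cspg4, whose place in both comparisons follows from the sort. The Notch pathway split, with 6 genes higher and 6 lower of 14 (median -0.29, percentile 18.22): the ligand Jag2 was endothelial (123 against 1.06 CPM), and the receptor Notch3 and its target Heyl were pericyte genes (2.88 against 1082 CPM, and 2.27 against 836). Vascular growth factors and receptors also went both ways, with 19 higher, such as Kdr, a receptor for vascular endothelial growth factor (613 against 2.09 CPM), and 10 lower, such as the sphingosine-1-phosphate receptor S1pr3 (4.02 against 1839), of 31 (median 1.50, percentile 100). The markers that named endothelial-like cells include the junction genes Cdh5 and Pecam1 and the growth factor receptor genes Flt1 and Tek, so the ranks of the junction and growth factor lists are no independent results either.

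Matrix genes divided by type: of 16 interstitial genes 11 were lower and 4 higher in endothelial-like cells (median -3.67, percentile 0), with the matrix-cleaving protease Mmp14 at 2.21 against 309 CPM. Of 15 basement membrane genes 3 were higher and 5 lower (median 0.00, percentile 55.52): fibronectin (Fn1) had 1088 against 12.3 CPM, and the laminin chain Lama2 0.866 against 697. Leukocyte adhesion and inflammation genes were higher in 9 and lower in 2 of 12 cases (median 2.29, percentile 99.94), led by the adhesion molecule Icam2 (492 against 1.40 CPM). Immediate early and stress genes were higher in 16 of 20 cases (median 1.86, percentile 100), the flow-responsive factor Klf2 most (513 against 10.3 CPM), and caveolae and transcytosis genes in 4 of 9 (median 1.00, percentile 98.06). Lipid and retinoid handling had 7 higher and 6 lower of 15 (median -0.12, percentile 43.59). Energy genes differed little: 19 of 21 oxidative phosphorylation genes (median -0.31, percentile 15.77) and 10 of 12 glycolysis genes (median -0.23, percentile 29.77) lay within 2-fold. The higher gene of the former list was Ndufa4, a subunit of the respiratory chain, with 215 against 14.1 CPM. Of 6 cell cycle genes 1 was higher and 1 lower (median 0.06, percentile 65.08). Xist, the counted member of the sex-linked check, had a log2 ratio of -0.62 (percentile 34.01).

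The median over all 11017 genes was -0.11, and median-of-ratios scaling would add 0.16 to every log2 ratio of this pair, 0.16 to the pair of the endothelial and mural lines, -0.18 to the Pdgfra-H2BGFP over Cldn5-eGFP pair and -0.15 to the pericyte-like over smooth muscle-like pair. Leaving out 1 plate moved the log2 ratio of Slco1a4 to 8.52 (without Mural3), Kdr to 8.35 and Heyl to -8.61 (without Mural4), and Icam2 to 8.30 and P2ry14 to -9.98 (without Mural5). With that scaling the median of lipid and retinoid handling turned from -0.12 to 0.04 here, that of cell cycle genes from -0.03 to 0.12 between the endothelial and mural lines, and that of oxidative phosphorylation genes from 0.07 to -0.11 between the Pdgfra-H2BGFP and Cldn5-eGFP lines.

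**Figure D2:**
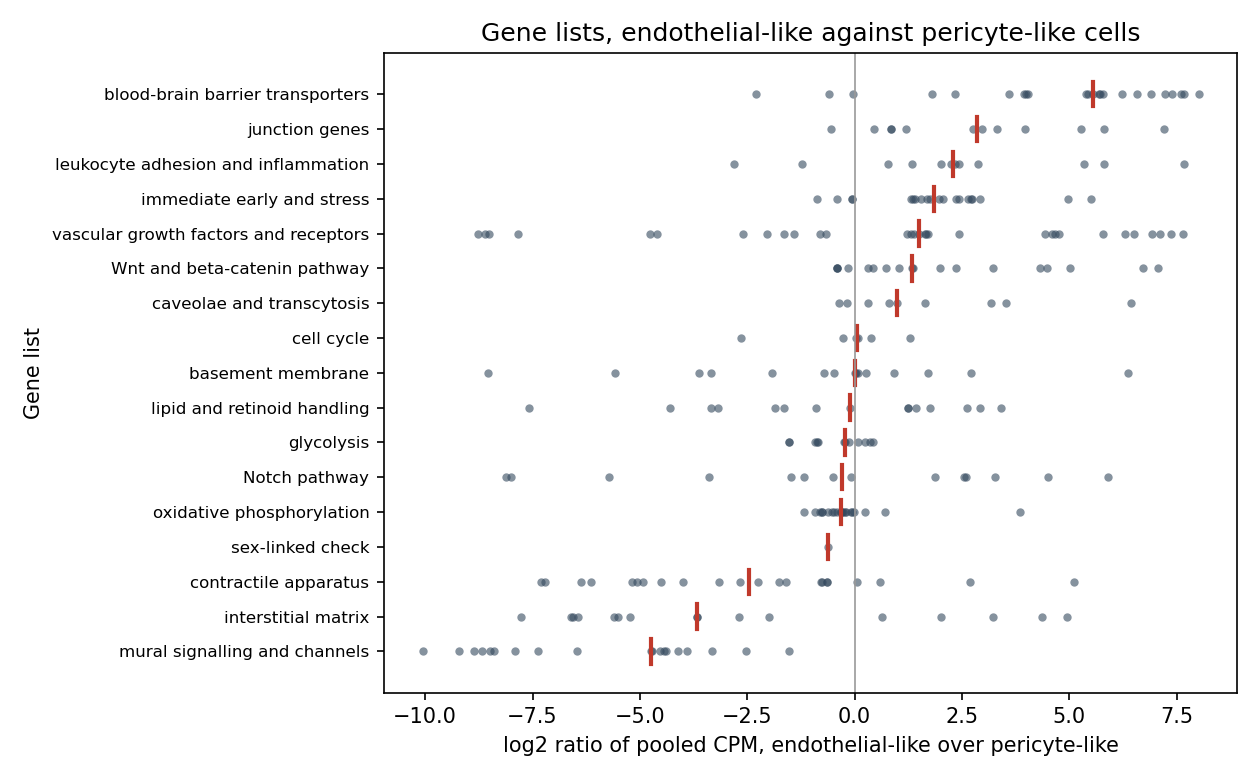
Log2 ratio of pooled CPM, endothelial-like over pericyte-like cells (x axis), for the members of each of the 17 gene lists (y axis) with at least 5 CPM in either class; each point is 1 gene and each red bar the median of its list. The blood-brain barrier transporters have a median of 5.55 and the genes of mural signalling and channels of -4.74.

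Along the arteriovenous axis, arterial-like cells differed from capillary-like cells in vessel-wall genes. The capillary-like cells include the sub-cluster of 360 cells led by Apln and Angpt2, whose name depends on the marker matching. Comparisons with capillary-like cells were not recomputed without it. Col18a1, a basement membrane collagen, had 174 CPM (172 to 177) in arterial-like and 4.77 (4.50 to 5.04) in capillary-like cells, Gper1, a membrane oestrogen receptor, 254 against 8.62 CPM, and Alpl, tissue-nonspecific alkaline phosphatase, 1403 against 125 CPM. All 9 counted interstitial matrix genes were at least 2-fold higher (median log2 ratio 3.95, percentile 100), such as fibulin 2 (Fbln2, 259 against 14.2 CPM) and elastin (Eln, 48.2 against 1.87). The 9 markers that named arterial-like cells include the matrix gene Mgp, so this rank is not fully independent of the naming. Of 12 Notch pathway genes 4 were higher and none lower (median 0.50, percentile 99.84), with the target Hey1 at 378 against 80.8 CPM and the ligand Jag2 at 248 against 93.6. Naming by arterial markers such as Efnb2 and Gja5 may favour this list too, here and against venous-like cells. Its ranks are therefore not fully independent of the naming. Barrier transporters were lower for 10 of 23 members and higher for 0 (median -0.99, percentile 0), among them the large neutral amino acid transporter Slc7a5 (416 against 1893 CPM, within plates -2.48 to -1.98) and Slc38a3 (327 against 1469). The cholesterol exporter Abcg1 and the angiopoietin gene Angpt2 were also lower (log2 ratios -2.94 and -4.69). Capillary-like cells were named by markers that include the transporter genes Mfsd2a and Slc16a1. The ranks of barrier transporters against them, here and for venous-like cells, are no independent results. Of 13 basement membrane genes 1 was higher and 3 lower, and all 12 junction genes lay within 2-fold.

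Venous-like cells were close to capillary-like cells in barrier transporters, all 23 of which lay within 2-fold (median log2 ratio -0.16, percentile 2.6). Capillary markers summed to 5930 CPM in venous-like, 7569 in capillary-like and 2709 in arterial-like cells. Venous markers summed to 4042 CPM in venous-like and 948 in capillary-like cells. A share of capillary cells in the venous-like class was not excluded. Venous-like cells also differed from capillary-like cells in single genes. They had more RNA of Adh1, an alcohol dehydrogenase (301 CPM, 298 to 305, against 41.2, 40.5 to 42.0), of the transmembrane protein gene Flrt2 (225 against 55.3) and of the leukocyte adhesion receptor Icam1 (341 against 82.6 CPM). Of 12 leukocyte adhesion and inflammation genes 4 were higher and 1 lower (median 0.63, percentile 100), the lower gene being the chemokine Cxcl12 (684 against 2308 CPM). Venous-like cells were named by markers that include the adhesion and cytokine receptor genes Vcam1 and Il1r1, so the rank of this list is no independent result. The Notch ligand Dll4 (57.7 against 244 CPM) and the target Hey1 (1.03 against 80.8) were lower. Set directly against venous-like cells, arterial-like cells had 7 of 12 Notch genes at least 2-fold higher (median 1.20, percentile 100), Hey1 with a log2 ratio of 7.54, and lower levels of Flrt2 (log2 ratio -5.93) and of Nrp2, a co-receptor for semaphorins (7.05 against 141 CPM). Of 13 leukocyte genes 2 were higher and 4 lower in arterial-like cells (median 0.04, percentile 54.74).

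All 4 Cldn5-eGFP plates held the 3 endothelial classes. Without EC5 the matrix proteoglycan gene Bgn, 1 of the 9 interstitial genes higher in arterial-like than capillary-like cells, turned from a log2 ratio of 2.03 to -0.59. Without EC4 the arterial over capillary log2 ratio of Angpt2 was -6.20, and the arterial over venous ratio of Flrt2 was -6.81; without EC5 that of Col18a1 over capillary-like cells was 4.31, without EC6 that of Eln was 4.80 and of Nrp2 over venous-like cells -4.80.

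**Figure D3:**
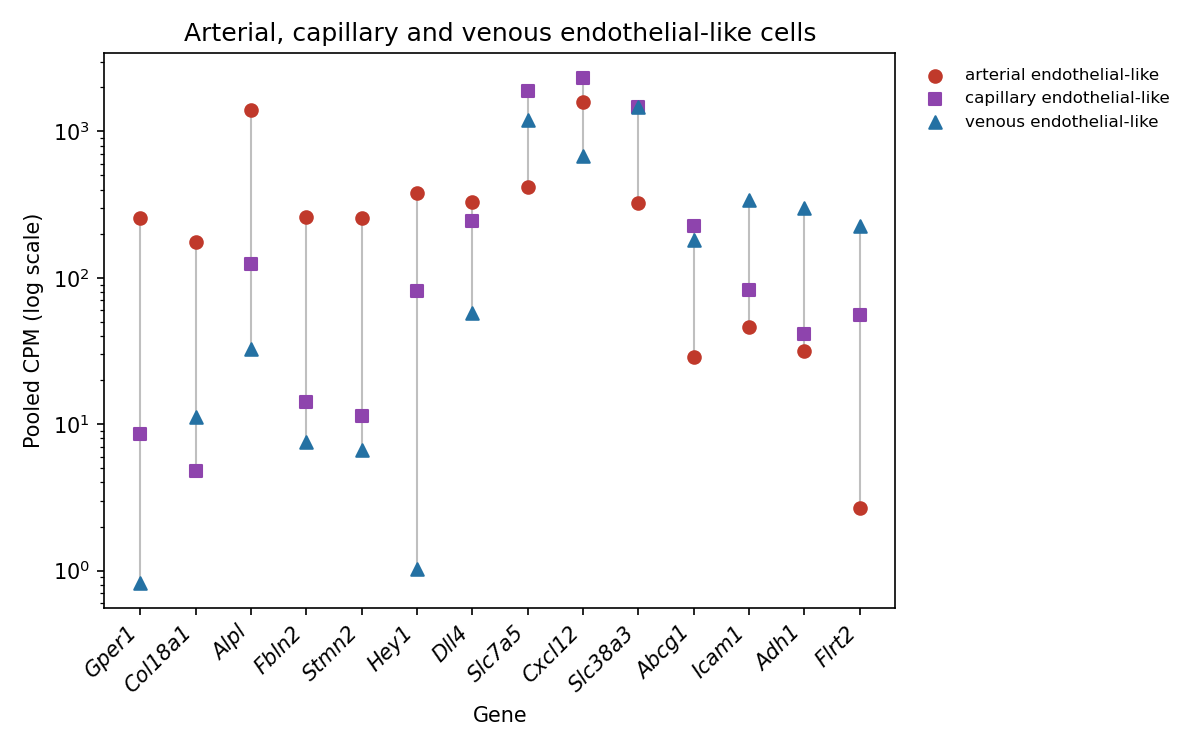
Pooled CPM on a log scale (y axis) of 14 genes (x axis) in arterial-like (circles), capillary-like (squares) and venous-like (triangles) endothelial cells, with a grey line over the range of the 3 classes. Hey1 has 378, 80.8 and 1.03 CPM in this order, and Icam1 46.2, 82.6 and 341 CPM.

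Mural cells were compared along the vascular tree, with 1181 pericyte-like against 173 smooth muscle-like cells, which shared 4 plates; ratios are pericyte-like over smooth muscle-like. Smooth muscle-like cells had higher contractile RNA: 21 of 25 genes were at least 2-fold higher in them and 0 lower (median log2 ratio -3.25, percentile 0), including Csrp1, a muscle LIM protein (14.0 CPM in pericyte-like cells against 2893, 95% interval 2880.1 to 2906), and the calcium release channel Ryr2 (0.457 against 134 CPM), while caldesmon (Cald1) had 2423 against 1923 CPM. The class was named by other contractile genes, such as Acta2 and Cnn1, so the naming itself favoured the direction of this list and its rank is no independent result. Ptgis, which makes prostacyclin, had 0.038 against 318 CPM. Among the genes that passed the naming rule, the sushi-domain gene Susd5 had the most negative log2 ratio (-8.84, within plates -8.96 to -8.71). Pericyte-like cells had more osteopontin (Spp1, 739 against 1.98 CPM), more of the Wnt antagonist Sfrp2 (182 against 0.406), of the glutamate receptor Grm3 (393 against 3.22) and of the growth factor pleiotrophin (Ptn, 2068 against 28.4 CPM). Of 18 barrier transporters 10 were higher in pericyte-like cells and 1 lower (median 1.62, percentile 100), Slc22a8 most (1396 against 8.11 CPM). A pseudocount of 10 CPM left 6 of the 10, and endothelial marker RNA was also higher in pericyte-like cells (4.28% against 0.103% of the endothelial-like level), so the list as a whole was not separated here from endothelial RNA.

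Genes of mural signalling and channels split between the mural classes, with 6 of 19 higher in pericyte-like cells and 4 higher in smooth muscle-like cells (median 0.06, percentile 47.54, and -0.09 with median-of-ratios scaling). Atp13a5 had 9959.7 against 369.8 CPM and P2ry14 2598 against 351, whereas the phosphodiesterase Pde3a had 31.6 against 346. Basement membrane genes were higher in pericyte-like cells for 6 of 15 members and lower for 2 (median 0.79, percentile 98.96): the laminin chains Lama2 (697 against 44.8 CPM) and Lamb1 (168 against 1.58) were higher, and Lama5 (25.8 against 629) and Col18a1 (12.6 against 249.6) lower. Of 20 interstitial genes 12 were higher in smooth muscle-like cells, such as elastin (Eln, 0.437 against 110.2 CPM), and of 8 caveolae genes 6, such as Ptrf, the caveolar coat gene also called Cavin1 (233 against 2825 CPM). Immediate early and stress genes were higher in smooth muscle-like cells for 19 of 20 members (median -3.71, percentile 0), with the transcription factor Fos at 105 against 10235 CPM. The median over all 10807 genes was 0.15. Leaving out Mural5 moved the log2 ratios of Slc22a8 to 7.97 and Lamb1 to 6.69, and leaving out Mural4 that of Fos to -7.27. In mm10 Csrp1 lies on chromosome 1 from 135720061 to 135752232.

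**Figure D4:**
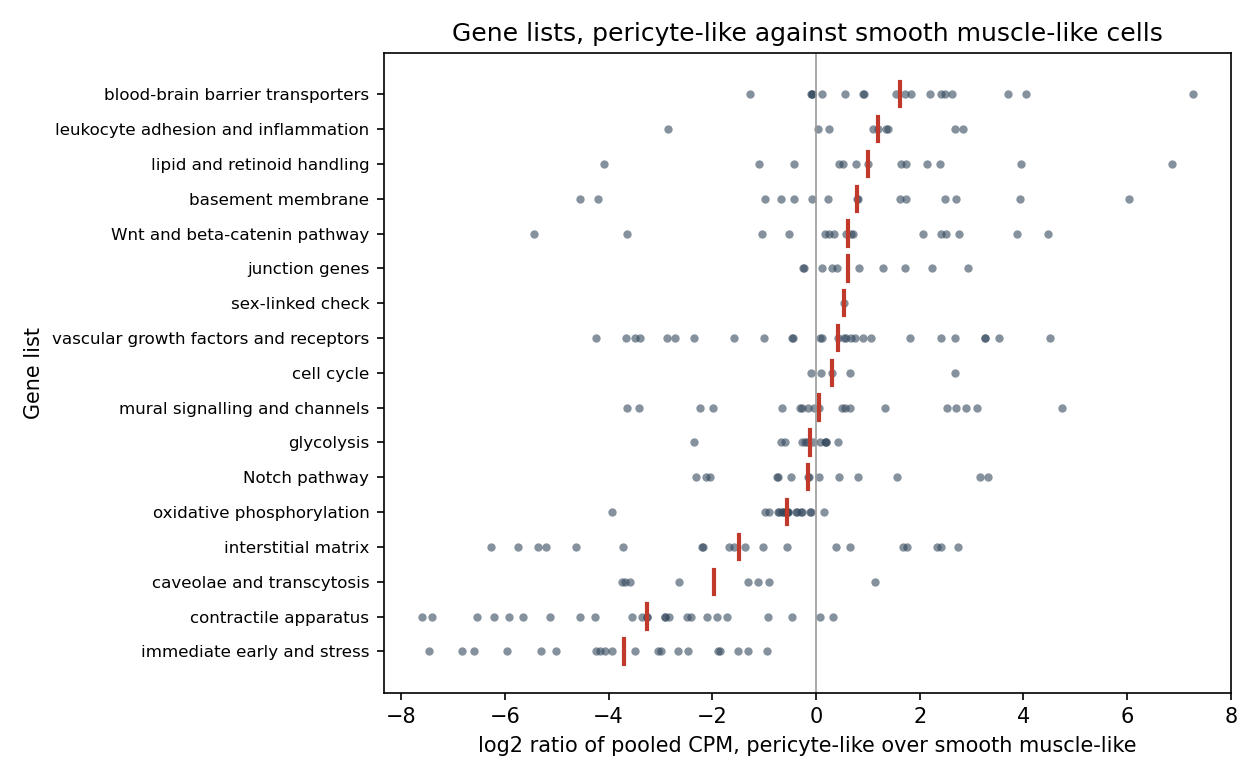
Log2 ratio of pooled CPM, pericyte-like over smooth muscle-like cells (x axis), for the members of each of the 17 gene lists (y axis) with at least 5 CPM in either class; each point is 1 gene and each red bar the median of its list. Immediate early and stress genes have a median of -3.71, contractile genes of -3.25 and barrier transporters of 1.62.

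The perivascular fibroblast-like cells were compared with pericyte-like cells, 78 against 1181 cells. Fibroblast-like cells had 23 of 25 interstitial matrix genes at least 2-fold higher and none lower (median log2 ratio 5.28, percentile 100): the collagen VI chain Col6a1 had 850.2 CPM (842 to 858, plates 558 and 886) against 0.424 (0.362 to 0.494), and Mfap4, on chromosome 11 from 61485431 to 61488900, had 1048 CPM against no read, at least 136649-fold higher by the same count of 3. The class was named by matrix markers outside the list, such as Col1a1 and Dcn, so the rank of this list too is no independent result. Lipid and retinoid handling was higher in 14 of 19 cases (median 3.48, percentile 100), with Ptgds at 9473 against 2.75 CPM, Apod at 13934 against 189 and the retinoic acid-forming enzyme gene Aldh1a2 at 147 against 1.37. Basement membrane genes went both ways, 6 higher and 4 lower of 16 (median 0.46, percentile 96.14), fibronectin (Fn1) at 773 against 12.3 CPM and the proteoglycan agrin (Agrn) at 87.5 against 399. The chemokine Cxcl1 had 484 against 6.20 CPM, and 9 of 12 leukocyte and inflammation genes were higher (median 2.82, percentile 99.99), as were 16 of 20 immediate early and stress genes (median 2.99, percentile 100).

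Pericyte-like cells kept the higher levels of mural genes: 19 of 21 for signalling and channels (median -2.83, percentile 0), led by Rgs4, a regulator of G protein signalling (0.195 CPM in fibroblast-like against 4036 in pericyte-like cells), and 7 of 12 Notch genes (median -2.35, percentile 0). Grm3 had 0.058 against 393 CPM, and Kcnmb1 had no read in fibroblast-like cells and 296 CPM in pericyte-like cells, at least 5080.3-fold lower. No plate held 10 cells of both classes, so class, line and plate changed together, and fibroblast-like cells were sequenced deeper (median 591077 against 334493 reads). Plate Pdgfra1 held 52 of the 78 fibroblast-like cells; without it the log2 ratio of Ptgds was 13.11 in place of 11.30, of Aldh1a2 7.14 in place of 5.96, of Fn1 4.50 in place of 5.87, of Agrn -1.31 in place of -2.18, of Col6a1 8.62 in place of 9.22 and of Mfap4 9.26 in place of 10.03. Leaving out Mural4 moved Cxcl1 to 6.83, and leaving out Mural3 moved Aldh1a2 to 6.65.

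Endothelial transcripts were read in other classes at unequal levels. The 8 endothelial markers summed to 701 CPM (698.6 to 704) in pericyte-like cells, 4.28% of the 16401 CPM of endothelial-like cells, and to 0.103% of it in smooth muscle-like cells. The level was 6.82% in fibroblast-like, 0.451% in oligodendrocyte-like cells (1.09% on Pdgfra1 and 0.014% on Pdgfra2) and 4.92% in microglia-like cells (2.75% to 11.8% with 1 plate left out). Emcn, the sialomucin endomucin of endothelium, made up most of the sum in pericyte-like and fibroblast-like cells: it had 488 CPM in pericyte-like cells, 34.7% of the 1407 CPM of endothelial-like cells, 72.6% of that level in fibroblast-like cells and 0.471% in smooth muscle-like cells. In pericyte-like cells the receptor gene Flt1 stood at 4.09% and Tek, the angiopoietin receptor, at 1.50% of the endothelial-like level, and the other 5 markers between 0.425% and 0.801%. On the 4 mural plates the pericyte-like level was 4.44%, 4.44%, 4.11% and 4.15%, and the smooth muscle-like level 0.084%, 0.045%, 0.221% and 0.053%. Without Emcn, an alternative chosen after seeing the data, the pericyte-like level was 1.42% and the fibroblast-like level 0.654%; the median over cells was 1.86% and 2.002%. Without Pdgfra1 the fibroblast-like level was 4.43%.

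**Figure D5:**
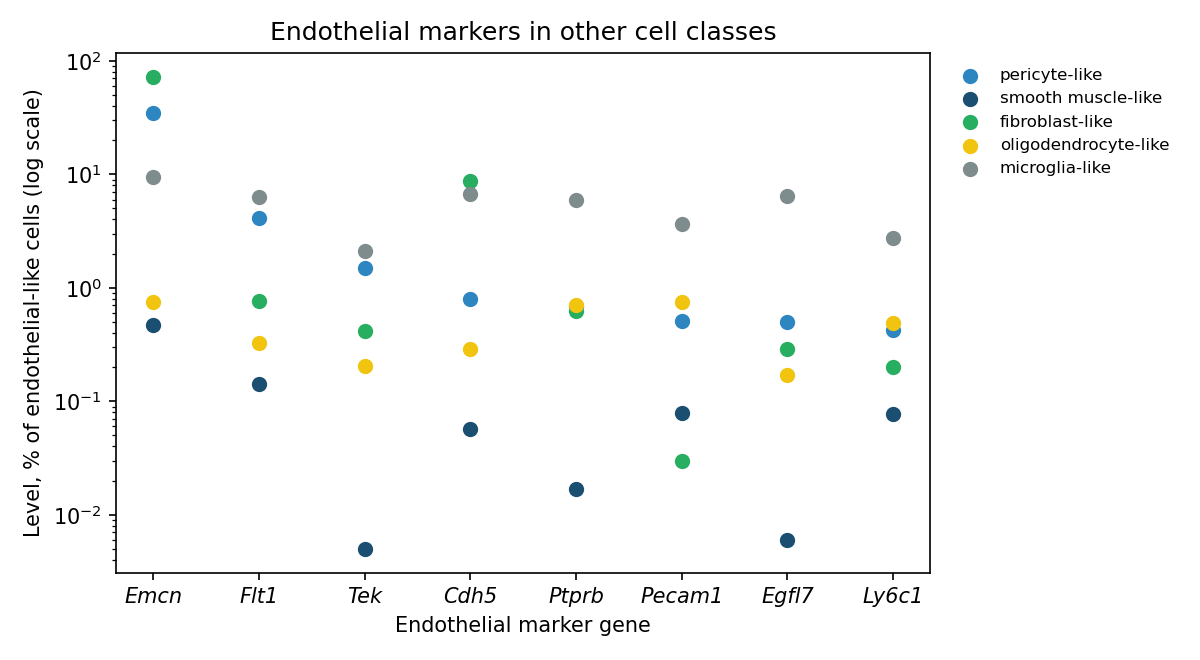
Level of the 8 endothelial marker genes (x axis) in 5 other cell classes, as percent of the level in endothelial-like cells on a log scale (y axis); each point is 1 gene in 1 class. Emcn stands at 34.7% in pericyte-like, 72.6% in fibroblast-like and 0.471% in smooth muscle-like cells.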

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

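Of the 8 tests below, the 3 on endothelial fragments and on a few cells with high counts were chosen before their result was seen; the other 5 were chosen only after it. Sets of 4 plates were compared 54 times and 2 values stood apart from the other 3 plates, about as many as 1 in 20 by chance. Microglia-like cells were 1.63% of plate Mural3 and at most 0.271% of the other mural plates. The genes of the vascular growth factor and receptor list summed to 5858 CPM on plate Mural6 and to 6201 to 6227 on the others. Y-linked genes summed to at most 0.702 CPM on 9 plates but were read clearly on plate Pdgfra2: the helicase gene Ddx3y at 34.7 CPM, Uty at 3.55, Kdm5d at 9.43 and the translation factor gene Eif2s3y at 53.4. With at least 10 reads, Xist marked 60 of its cells, Y-linked genes marked 43, no cell had both and 47 had neither, so this plate held cells of both sexes.

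Pericyte-like cells held endothelial marker RNA at 4.28% of the endothelial-like level. Free endothelial RNA in the suspension would reach smooth muscle-like cells of the same plates too, but their level was lower by at least 18.7 times on every plate. If endothelial fragments or second cells had brought Emcn, the 5% of pericyte-like cells richest in 5 endothelial markers would hold much of it, yet these 59 cells held 5.87% of the Emcn RNA. They held 46.3% of the RNA of 10 other endothelial genes, which is consistent with fragments as a source of those genes. No biological explanation was tested, so transcription of Emcn in pericytes stays open.

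In the Pdgfra-H2BGFP line eGFP was read in 13 of 26 fibroblast-like but 2 of 117 oligodendrocyte-like cells of plate Pdgfra2. Lower depth does not account for it: oligodendrocyte-like cells were read deeper on both plates (medians 1016402 against 872052 reads on Pdgfra1 and 477140 against 171057 on Pdgfra2), and with all cells of plate Pdgfra1 thinned to 100000 reads, eGFP was read in 78.8% (65.3 to 88.9) of 52 fibroblast-like and 15.8% (6.02 to 31.3) of 38 oligodendrocyte-like cells. Cells without the reporter that passed the sort cannot be told apart from cells with little reporter RNA: endothelial-like and microglia-like cells made up 5.45% of the line. Reporter protein outlasting its RNA as oligodendrocyte progenitors mature was not tested and may remain.

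Immediate early and stress genes were higher in smooth muscle-like than in pericyte-like cells. Both classes lay on the same 4 plates, so handling of whole plates could not by itself set them apart. A difference carried by some plates alone would leave the others near 0, but the plate median nearest to 0 was -3.12, with -3.44, -3.88 and -4.12 on the others. Handling that was alike on all plates was not addressed by these values. A few cells with very high counts would leave the median cell unchanged, yet the median smooth muscle-like cell had 25.1 times the list sum of the median pericyte-like cell. A response to cell isolation cannot be told apart from signalling in the living vessel without cells that were not isolated. The 3 heat shock genes of the list were higher in smooth muscle-like cells, with a median log2 ratio of 2.65 (Hspa1a 3.48, Hsp90aa1 1.32). They belong to the list that set the pattern, so they are no separate evidence and cannot decide this question. No biological explanation was tested.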

How the results depend on the processing

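Chosen only after the data were seen, and called added below, were 8 alternatives: 1 marker of another class leaving a cluster unnamed, unnamed sub-clusters kept (in 3 comparisons), endothelial-like cells of the Cldn5-eGFP plates alone, mural sub-cluster 5 left out, fibroblast-like cluster 12 left out, and Emcn left out. Counted as values, 1 per result and setting, planned settings kept 76 of 98 values of 9 class shares, 391 of 395 of 26 list counts, 367 of 395 of 26 list medians, 8250 of 8846 of 603 gene log2 ratios (20 changed sign) and 18 of 33 of 5 marker levels. Added ones kept 8 of 9, 20 of 20, 18 of 20, 386 of 456 and 2 of 5 values. For all values that moved or turned, the cause was not tested. A share was kept if it stayed in the exact interval of the main setting, and a list count if it changed by at most 3/2 times. A list median was kept if it moved by less than 0.5, and a gene log2 ratio if by less than 1 without a change of sign. A marker level was kept if it moved by at most 1 standard deviation over plates. Resolutions 0.5 and 2 and clustering on the authors' values gave class shares alone. Resolution 0.5 gave 64.9% capillary-like and 0.0% venous-like; resolution 2 gave 89.8% endothelial-like in the Cldn5-eGFP line, 4.25% in the Pdgfrb-eGFP/NG2-dsRed line, 4.33% arterial-like and 48.9% capillary-like. All genes as features gave 7.64% arterial-like, 34.2% capillary-like and 22.8% venous-like, and Pde5a venous over capillary 0.24 (was -1.08). With at least 2000 genes per cell pericyte-like cells were 76.7%, smooth muscle-like 14.8%, arterial-like 20.7% and capillary-like 40.2%. The authors' values gave 79.8% pericyte-like, 66.2% capillary-like, 13.2% venous-like and a microglia-like marker level of 6.12%; with them, and with the mean of per-cell CPM, Pfkp fibroblast-like over pericyte-like was 0.008 (was -1.24). Without mixed wells the Pdgfra-H2BGFP line was 20.3% fibroblast-like and 72.6% oligodendrocyte-like. Letting 1 marker of another class leave a cluster unnamed (added) gave 27.97% capillary-like. The within-plate mean turned Col18a1 (-2.33) and Ch25h (-1.96) for endothelial-like over pericyte-like and Myl9 for venous over capillary (0.013), and gave no value for fibroblast-like over pericyte-like. Without a list minimum 5 basement membrane genes were lower in arterial-like than capillary-like cells; a pseudocount of 10 CPM left 2 leukocyte genes lower in arterial-like than venous-like cells and 6 barrier transporters higher in pericyte-like than smooth muscle-like cells. The median over cells set the endothelial marker level at 1.86% (pericyte-like), 0.013% (smooth muscle-like), 2.002% (fibroblast-like) and 1.26% (microglia-like); leaving out the most abundant marker at 5.86% (pericyte-like), 9.55% (fibroblast-like) and 5.81% (microglia-like); leaving out Emcn (added) at 1.42%, 0.654% and 4.50%. Leaving out 1 plate gave ranges of 17.3% to 48.6% fibroblast-like, 35.5% to 78.0% oligodendrocyte-like, 12 to 21 interstitial matrix genes higher than in the mural line, marker levels of 4.43% to 7.12% (fibroblast-like) and 2.75% to 11.8% (microglia-like), and log2 ratios for Pdgfra-H2BGFP over Cldn5-eGFP of -0.55 to 3.15 (Slc29a1), -1.45 to 2.01 (Col14a1) and -0.003 to 5.76 (Eif2s3y), over Pdgfrb-eGFP/NG2-dsRed of -1.26 to 1.69 (Slco2b1), -0.94 to 3.00 (Itga8), -1.25 to 2.43 (Fn1), -0.065 to 2.10 (Col18a1), -1.61 to 1.64 (Tgfbr1), -1.97 to 3.10 (Socs3), -0.042 to 2.85 (Egr1) and -0.65 to 2.64 (Fosb), for arterial over capillary of -0.59 to 2.69 (Bgn), and for fibroblast-like over pericyte-like of -1.48 to 6.02 (Slco2b1) and -1.96 to 0.85 (Pfkp). No paired analysis was possible because the labels name no animal and no result has a test; the within-plate values pair classes by plate only, as a technical check.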

Other observations

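The genes of this part were chosen after their values were seen, and nothing in it was tested; all its contrasts were chosen only after the result was seen. Ndufa4, a subunit of the respiratory chain, had 14.1 CPM in pericyte-like cells against 215 in endothelial-like, 229.8 in smooth muscle-like, 102 in fibroblast-like and 151 in oligodendrocyte-like cells. Its paralogue Ndufa4l2, a hypoxia-inducible gene, went the other way, with 650.1 CPM in pericyte-like cells, 2.56 in endothelial-like, 143 in smooth muscle-like, 16.4 in fibroblast-like and 0.132 in oligodendrocyte-like cells. Car4, a membrane carbonic anhydrase, had 46.4 CPM in arterial-like, 1798 in capillary-like and 2119 in venous-like endothelial cells, and 1962 in pericyte-like cells. Ndufa4l2 is among the markers that named pericyte-like cells, and Car4 among those that named capillary-like cells. Their levels in these classes are therefore no independent result. The organic anion transporter gene Slc22a8 was shared by endothelial-like and pericyte-like cells (1350.5 and 1396 CPM) and nearly missing from smooth muscle-like cells (8.11 CPM).

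A mural sub-cluster of 135 cells, counted as pericyte-like, lay between the other pericyte-like sub-clusters and the smooth muscle-like class in its Acta2 RNA. Acta2 and Myh11 are among the markers that named smooth muscle-like cells, so their high levels in that class are no independent result. The actin gene Acta2 had 3051 CPM in it, between 7.63 and 48.9 in the other pericyte-like sub-clusters and 30626 in smooth muscle-like cells, and it also had Myh11, the smooth muscle myosin heavy chain (819 CPM), Car4 (3454 CPM) and the epoxide hydrolase gene Ephx3 (602 CPM). The unnamed sub-cluster of 35 mural cells had the transcription factor gene Fos at 7819 CPM, the apolipoprotein gene Apoe at 2663 and the matrix Gla protein gene Mgp at 5059. The unnamed endothelial-like sub-cluster of 192 cells had the choroid plexus gene Ttr at 234 CPM, and the astrocyte genes Slc1a2 at 81.1 and Aldoc at 75.4, each read in few of its cells.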
